A study of Mus musculus with 14 samples.

How the data were processed

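RNA of 14 samples of mouse primary cortical neurons was hybridised to Affymetrix mouse whole-genome 3' arrays, 1 array per sample, from 7 ug of RNA per the labels. The neurons were dissociated from the cortex of Swiss albino embryos at gestational day 15 to 16 and treated on day 7 in vitro. Groups were taken from the sample labels: vehicle (5 arrays) and NOC-18 for 8, 15 and 24 h (3 arrays each).

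The arrays were processed with MAS5, per the submitters' processing notes, and no version was given in the sources used here. The deposited value table holds a linear ratio for each of 45101 probe sets: each value is the signal divided by the probe set's arithmetic mean over the 5 vehicle arrays, since that mean departs from 1 by at most 2.28e-07. No signal level or detection call can be read from such ratios, so weak and strong transcripts could not be told apart, and noise of weak probe sets appears as large ratios. The lowest value, 0.01, was held by 7 cells. The scaling of the deposited table was kept, and no per-sample column was left unused.

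The tests had been planned for signals, with a pseudocount, a filter on low values and the brightest probe set per gene. None of these has a meaning for ratios, so log2 of the ratio was used with no pseudocount and no filter, and the log2 values of all probe sets of a gene were averaged. Probe sets were named through the platform annotation: 34945 had 1 gene symbol, 932 had several and 9160 had no entry, and 64 control probe sets were left out. Symbols were updated through the RefSeq gene table of mouse assembly GRCm38.p6, whose coordinates were not used. This gave 18193 genes, 9183 of them with 1 probe set.

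Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 14 arrays, then eBayes), two-sided, with Benjamini-Hochberg adjustment over 18193 genes and a threshold of 0.05. The prior degrees of freedom were 1.84, so that the variance of a gene was little moderated. Each time was compared with vehicle, 15 h with 8 h and 24 h with 15 h, and a moderated F test covered the 3 times. On simulated data with the spread of these arrays (24 h against vehicle, 18193 genes), 28.4% of genes changed by a log2 of 1 and 59.8% of those changed by a log2 of 2 were recovered, and 5.77% of calls were false.

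Before the data were examined, 24 gene lists with 477 genes were fixed from textbook knowledge, of which 453 genes were measured: p53 targets, NRF2 antioxidant genes, cytosolic heat shock genes, ATF4 and CHOP targets, ER chaperones, proteasome subunits, autophagy and lysosome, apoptosis machinery, immediate early and activity genes, synaptic transmission, GABAergic interneuron markers, neuronal cytoskeleton and identity, astrocyte, microglia, oligodendrocyte lineage, and vascular and meningeal markers, cell cycle genes, NF-kB and cytokine genes, respiratory chain subunits, HIF1 targets and glycolysis, cholesterol synthesis, metallothionein, zinc and iron, DNA repair, and nitric oxide signalling. None of the astrocyte or oligodendrocyte markers was in another list (0 and 0 genes). Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over 72 tests against vehicle and over 48 between times, and again with the correlation estimated. In 21 of the 120 list tests the median, the mean and the test differed in sign, and 0 of those 21 were called. In the simulation 0 of 120 unchanged lists were called, but simulated genes varied independently, which real genes do not.

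Named genes followed a rule set at the same time: the 8 largest increases and decreases per time against vehicle among called genes whose treated arrays all lay beyond all vehicle arrays, the 4 largest in each direction between successive times, the 3 members of each list with the smallest F test p, and Hmox1, Cdkn1a, Ddit3, Fos, Bdnf and Nos1. Other members of the lists, and the genes with opposite changes, were named after their values were seen. Array quality was checked with the 3' to 5' ratios of the beta-actin and Gapdh control probe sets, by exact permutation tests, and with the hybridisation controls. A bound of 0.9 on the mean ratio of the latter was set after seeing the data.

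Alternatives were 3 pseudocounts, quantile normalization, median centring, single probe sets, the probe set with the least vehicle spread, eBayes with trend and robust variances, array weights, the replicate number as a block, the 40% of genes with the largest spread left out, the hybridisation-control split as a block, the 10 arrays with higher controls, only the arrays of the groups compared, and each array left out in turn. Overlaps were set beside 100 simulations of unchanged groups and beside 20 splits of the vehicle arrays. Plots were drawn with matplotlib 3.10.9.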

Results

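Transcript levels were measured on 14 Affymetrix mouse whole-genome arrays, 1 per sample, of primary cortical neurons taken from embryos of Swiss albino mice and kept in culture for 7 days. The 5 vehicle samples were set against cultures exposed to NOC-18, a compound that releases nitric oxide as it decays, for 8, 15 or 24 h, with 3 samples at each time. The series was made to profile transcription while nitric oxide kills neurons. The concentration of NOC-18 and the harvest time of the vehicle cultures were not given in the sources used here. Exposure to NOC-18 therefore cannot be told apart from time in culture. Each deposited value was a ratio of a probe set to its own mean over the vehicle arrays, so changes could be measured but absolute levels could not. The number of arrays limits the precision. The labels did not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Changes are given below as log2 fold changes with the standard error (SE) of the fit, for 3 treated arrays against 5 vehicle arrays unless stated, and every adjusted p is Benjamini-Hochberg adjusted.

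The lowest median ratio of an array was 0.842, in 24 h replicate 1, and the highest was that of vehicle replicate 1. No 2 replicates of a group shared identical values, and the SD of the log2 difference between 2 replicates was 0.966 to 1.15 over the 18193 genes. The ratios of 3' to 5' control probe sets of beta-actin and Gapdh, a sign of RNA breakdown, gave two-sided exact permutation p values from 0.196 to 0.554 for the treated times against vehicle (n = 3 against 5, 56 splits, 6 tests, smallest adjusted p = 0.455). Hybridisation controls, bacterial and phage transcripts spiked into each sample, separated the arrays in a way the groups did not explain. They stood at 0.689 to 0.821 in vehicle replicates 4 and 5, 8 h replicate 3 and 24 h replicate 1, and at 1.00 to 1.37 in the other 10 arrays. No 15 h array was among the 4 lower ones, and 486 genes (2.67%) differed with this split in limma's moderated test with the groups in the model.

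The first comparison asked what had changed after 8 h of NOC-18. Immediate early genes, which neurons switch on within minutes to hours of stimulation, were among the genes that rose. Fos, a subunit of the AP-1 transcription factor, rose 30.8-fold (log2 fold change 4.95, SE 0.30, adjusted p = 1.43e-05 by limma's moderated test). Nr4a1, an orphan nuclear receptor, rose 9.65-fold (3.27, SE 0.18, adjusted p = 1.23e-05), and Hmox1, the heme-degrading enzyme heme oxygenase 1, rose 22.3-fold (4.48, SE 0.49, adjusted p = 0.00143). Olig1, a transcription factor of the oligodendrocyte lineage, fell by 1.41 on the log2 scale (SE 0.17, adjusted p = 0.00367).

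Of 18193 genes, 71 were higher and 112 lower at 8 h, and 64 and 56 of them by at least 2-fold. Centring each array on its median turned this balance, with 86 higher and 62 lower (41.9% lower against 61.2%), and quantile normalization gave 50 and 34 (40.5% lower). The counts rested on single arrays: without 8 h replicate 2 they were 17 and 6, without 8 h replicate 1 34 and 12, without 8 h replicate 3 39 higher, and without vehicle replicates 1 and 2 in turn 45 and 36, and 41 and 40. The lower genes were also fewer without vehicle replicate 3 (38), vehicle replicate 4 (56) and each 15 h array (62, 57 and 59). With the hybridisation-control split as a block the counts were 110 and 256, and on the 10 arrays with higher controls they were 51 and 56. The eBayes fit with a trend and robust variances left 27 higher and 3 lower.

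Of the 20 immediate early and activity genes measured, 16 rose at 8 h, none fell and 4 did not pass, while 19 rose when adjusted over the list alone. The list moved up against all other genes (camera adjusted p = 4.67e-46, median 2.52), and its call held with an estimated correlation (adjusted p = 0.000555). Members included Fosb (4.36, SE 0.43) and Jun (2.57, SE 0.18), further AP-1 subunits, Egr2 (3.56, SE 0.30), a zinc finger factor, and Npas4 (4.55, SE 0.81), a factor induced by neuronal activity. Bdnf, a neurotrophin gene driven by activity, rose by 1.57 on the log2 scale (adjusted p = 0.0266), a call lost without vehicle replicate 1 or 2 or any 8 h array (highest adjusted p = 0.124). Npas4 was lost without vehicle replicate 2 or any 8 h array (highest adjusted p = 0.110), whereas Fos, Fosb, Jun, Egr2, Nr4a1, Hmox1 and Olig1 were called in all 14 fits that left out 1 array. The 16 members that rose numbered 10 without 8 h replicate 1 or 2.

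Among 20 targets of NRF2, the factor that answers oxidative and electrophilic stress, 4 rose at 8 h, none fell and 16 did not pass (4 adjusted over the list alone). The list rose with camera adjusted p = 1.38e-08 (median 0.33), a call lost at adjusted p = 0.211 with an estimated correlation. Besides Hmox1, the members were Osgin1 (4.31, SE 0.71), an oxidative stress-induced growth inhibitor, Srxn1 (1.81, SE 0.24), which repairs oxidised peroxiredoxins, and Slc7a11 (1.80, SE 0.26), the cystine transporter. Without 8 h replicate 2, Srxn1 (adjusted p = 0.0545), Slc7a11 (0.0775) and Osgin1 (0.0952) were no longer called, and Osgin1 also not without 8 h replicate 1. Of 26 ATF4 and CHOP targets, genes of the integrated stress response, 3 rose (Ddit3, which encodes CHOP, Slc7a11 and the transcription factor gene Cebpb), none fell and 9 rose when adjusted over the list alone (camera adjusted p = 4.63e-06). That list call was lost at adjusted p = 0.432 with an estimated correlation. Ddit3 rose by 1.35 (SE 0.25, adjusted p = 0.0311), with the call lost without any 8 h or 15 h array or vehicle replicate 1 or 2 (highest adjusted p = 0.151), and Cebpb was called only without vehicle replicate 5 or 24 h replicate 1 (highest adjusted p = 0.192 otherwise). Among 22 p53 targets only Btg2, which is also an immediate early gene, rose (1.42, SE 0.21), against 3 adjusted over the list alone, with camera adjusted p = 7.51e-05 and adjusted p = 0.211 with an estimated correlation. Without 8 h replicate 1 or 2 Btg2 was not called (highest adjusted p = 0.0822). The NRF2 members that rose numbered 1 without 8 h replicate 2. Those of ATF4 and CHOP numbered 0 without 8 h replicate 2, 1 without vehicle replicate 1 or 2 or 8 h replicate 1 or 3 or any 15 h array and 6 without vehicle replicate 5. The p53 members that rose numbered 0 without 8 h replicate 1 or 2 and 3 without vehicle replicate 5.

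The other 20 lists did not pass camera at 8 h. Of the NF-kB and cytokine genes 2 of 17 rose, namely Ptgs2 (4.36, SE 0.85), the inducible cyclooxygenase, and the chemokine gene Cxcl10 (1.58, SE 0.28). With 1 array left out, the Ptgs2 call held only without vehicle replicate 3 or 5 or 24 h replicate 1 (highest adjusted p = 0.156 otherwise), and that of Cxcl10 was lost without vehicle replicate 2 or 3 or any 8 h array (highest adjusted p = 0.132). Of the HIF1 and glycolysis list Slc2a1, the glucose transporter GLUT1, rose (1.67, SE 0.33), a call that held only without vehicle replicate 5 or 24 h replicate 1 (highest adjusted p = 0.166 otherwise). Olig1 was the 1 of 12 oligodendrocyte lineage markers that fell (camera adjusted p = 0.103). No member was called among the heat shock, ER chaperone, proteasome, autophagy, apoptosis, synaptic, interneuron, neuronal cytoskeleton, astrocyte, microglia, vascular, cell cycle, respiratory chain, cholesterol, metallothionein, DNA repair or nitric oxide signalling lists. The synaptic list passed with the hybridisation-control split as a block (adjusted p = 0.0291) and not without it (0.114), nor with an estimated correlation (0.90). The largest decreases outside the lists were those of Mfsd4b4 (-3.30, SE 0.40) and Cpm (-2.45, SE 0.37), and Cpm was not called without 8 h replicate 1 or 2 (highest adjusted p = 0.0723). HIF1 and glycolysis genes that rose numbered 0 without vehicle replicate 1, 2, 3 or 4 or 24 h replicate 2 or 3 or any 8 h or 15 h array and 2 without vehicle replicate 5. Without vehicle replicate 5, 1 heat shock gene and 1 apoptosis gene rose and 1 cell cycle gene fell.

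**Figure D1:**
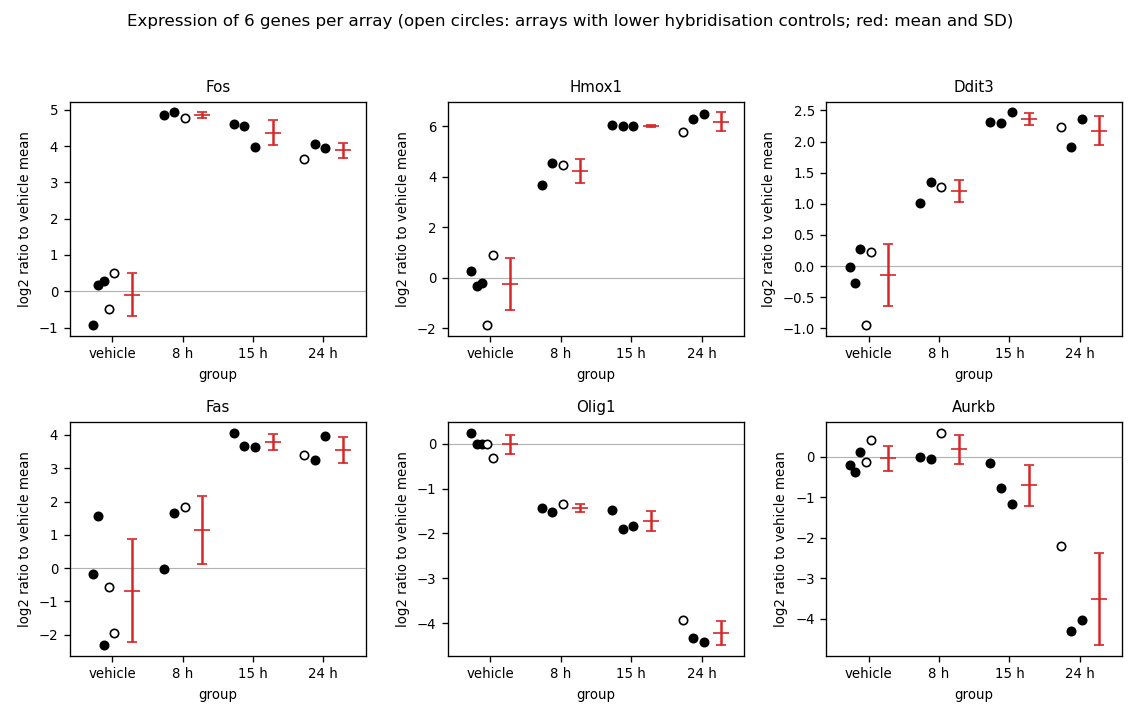
Each panel plots the log2 ratio to the vehicle mean of 1 gene on each of the 14 arrays by group (vehicle, then NOC-18 for 8, 15 and 24 h), with open circles for the 4 arrays with lower hybridisation controls, filled circles for the others, and red marks for the group mean and SD. Fos was 4.95 above vehicle at 8 h and 3.98 at 24 h, Hmox1 rose to 6.41 at 24 h, and Olig1 and Aurkb lay -4.22 and -3.48 from vehicle at 24 h.

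The second comparison set 15 h of NOC-18 against vehicle. Hmox1 rose 76.3-fold (log2 fold change 6.25, SE 0.49, adjusted p = 6.02e-05 by limma's moderated test), and Ptgs2 rose 82.4-fold (6.36, SE 0.85, adjusted p = 0.00119). Fas, a death receptor and p53 target, rose 22.3-fold (4.48, SE 0.75, adjusted p = 0.00311), and Slc2a1 rose 11.1-fold (3.47, SE 0.33, adjusted p = 0.000211). Tk1, the thymidine kinase of dividing cells, fell by 3.72 on the log2 scale (SE 0.63, adjusted p = 0.00349). Esm1, a secreted endothelial proteoglycan, rose by 5.63 (SE 0.74), and Tsnaxip1 and Calhm2 stood at -3.39 (SE 0.46) and -2.99 (SE 0.44). All 8 were called in each of the 14 fits that left out 1 array.

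At 15 h 619 genes were higher and 1587 lower (71.9% lower), of which 380 and 590 by at least 2-fold. The median of all genes was -0.097, and 0.042 after median centring, which gave 989 higher and 1031 lower (51.0% lower). Quantile normalization gave 256 and 346 (57.5% lower). Without 15 h replicates 1, 2 and 3 in turn, the counts were 261 and 725, 357 and 886, and 401 and 947. With the hybridisation-control split as a block they were 665 and 1921, and on the 10 arrays with higher controls 737 and 1583. The lower-control set held no 15 h array.

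Of 20 NRF2 targets 13 rose at 15 h, none fell and 7 did not pass (15 adjusted over the list alone, camera adjusted p = 1.06e-17), and the list call was lost at adjusted p = 0.0566 with an estimated correlation. The members included Srxn1 (2.82, SE 0.24), Slc7a11 (2.90, SE 0.26), the glutathione transferase gene Gsta4 (2.60, SE 0.23) and Gclm (2.17, SE 0.32), a subunit of the enzyme that limits glutathione synthesis. Of 20 immediate early genes 14 rose and none fell (18 adjusted over the list alone, camera adjusted p = 6.45e-23, median 1.70), and this call held with an estimated correlation (adjusted p = 0.00556). Bdnf, at 0.89 (SE 0.28, adjusted p = 0.0623), was not among them. Of 26 ATF4 and CHOP targets 10 rose and none fell (12 adjusted over the list alone, camera adjusted p = 1.78e-08), a call lost at adjusted p = 0.283 with an estimated correlation. They included Ddit3 (2.50, SE 0.25) and Ppp1r15a (1.51, SE 0.22), a phosphatase subunit that restores translation. The ATF4 and CHOP targets that fell numbered 1 without vehicle replicate 4.

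Among 22 p53 targets 8 rose and none fell at 15 h, and 11 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.06e-07). The call was lost at adjusted p = 0.102 with an estimated correlation. They included Bbc3 (1.40, SE 0.22), which encodes the death-promoting protein PUMA, and Ccng1 (1.21, SE 0.23), a cyclin, while Cdkn1a, the classic p53 target that halts the cell cycle, stood at 1.17 (SE 0.45, adjusted p = 0.125). Of 17 NF-kB and cytokine genes 3 rose and none fell (3 adjusted over the list alone, camera adjusted p = 0.00510, lost at adjusted p = 0.0558 with an estimated correlation), and Cxcl10 was 1 of them (2.24, SE 0.28). Of 20 autophagy and lysosome genes 3 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00532), with adjusted p = 0.487 with an estimated correlation. Sqstm1, the autophagy receptor p62, led them (2.45, SE 0.32), and Ulk1, a kinase that starts autophagy, fell by 0.97 on the log2 scale, a call lost without 15 h replicate 1 (adjusted p = 0.0596). With 1 array left out, the autophagy members that rose numbered 5 without 24 h replicate 1.

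Of 15 astrocyte markers 11 rose at 15 h, none fell and 4 did not pass (13 adjusted over the list alone, median 1.10, camera adjusted p = 5.23e-10), and the call was lost at adjusted p = 0.102 with an estimated correlation. Gja1, the gap junction protein connexin 43, rose by 1.28 (SE 0.21) and Aldoc, the brain aldolase, by 1.30 (SE 0.25). Clu, a secreted chaperone, rose by 1.15 (SE 0.24), a call lost without 15 h replicate 1 (adjusted p = 0.0535). The 11 astrocyte genes that rose numbered 3 without 15 h replicate 1 and 7 without vehicle replicate 2 or 5 or 15 h replicate 2. Of 12 oligodendrocyte lineage markers 5 fell and none rose (5 adjusted over the list alone, median -0.88, camera adjusted p = 0.00312), with adjusted p = 0.150 with an estimated correlation. They were Olig1 (-1.72, SE 0.17), Olig2 (-1.78, SE 0.33), Cspg4, Sox10 and Gpr17 (-1.98, SE 0.54), and Gpr17 was not called without 15 h replicate 1 or 2 or vehicle replicate 1, 3, 4 or 5 (highest adjusted p = 0.149). Cspg4 was not called without vehicle replicate 1, 2 or 4 or any 15 h array (highest adjusted p = 0.109), and Sox10 was called only without vehicle replicate 2, 8 h replicate 3 or 24 h replicate 1 (0.176 otherwise). The 5 lower members numbered 2 without vehicle replicate 1 or 4 or 15 h replicate 1 or 2 and 3 without vehicle replicate 3 or 5 or 15 h replicate 3.

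No other list passed camera at 15 h. Within them, 2 of 17 heat shock genes rose (Hspb8, 2.54, SE 0.35, and Hspa8) and Chordc1 fell. Of 22 apoptosis genes 4 rose and 3 fell, and those that rose included Fas, Bbc3 and Pmaip1, which are also in the p53 list. Of 19 members of the ER chaperone list 1 rose (Herpud1, 1.15, SE 0.18) and 4 fell. The respiratory chain gene Cox7c rose (1.30, SE 0.22), as did Atp5c1, among 27 measured. Adm, the vasodilator peptide adrenomedullin, and Slc2a1 were the 2 of 21 HIF1 and glycolysis genes that rose, Adm by 3.60 (SE 0.51). The metallothionein, zinc and iron list had 2 members higher and 3 lower of 13, with Ireb2, an iron regulatory protein, at -0.85 (SE 0.14). Of 31 proteasome subunits 1 rose and 2 fell, and of 22 cell cycle genes 2 rose and 3 fell. Of 22 synaptic genes 2 fell (Slc17a7 and Dlg4), of 16 interneuron markers 2 fell (Dlx1, -1.44, SE 0.27, and Vip), 1 of 15 microglia markers rose (Cd68), and 1 of 15 cholesterol genes fell (Mvd). The synaptic list, at adjusted p = 0.0653 with camera, passed with the hybridisation-control split as a block (0.00205) and on the 10 arrays with higher controls (0.00224). In these settings 9 and 8 of its 22 genes were called lower and 0 higher. The neuronal cytoskeleton list (0.0448 and 0.0322, against 0.527) and the microglia list (0.0229 and 0.0273, against 0.678) also passed in both. The microglia median turned from -0.25 to 0.21 with the block. With an estimated correlation, in all arrays, adjusted p was 0.90 for each of the 3. No member was called among 16 neuronal cytoskeleton genes, 16 vascular markers, 20 DNA repair genes or 18 nitric oxide signalling genes. Nos1, the neuronal nitric oxide synthase, stood at -0.49 (SE 0.26, adjusted p = 0.276 by limma's moderated test). Leaving out 1 15 h array ended the calls of Psma3 and Atp5c1 (replicate 1 or 2, highest adjusted p = 0.101 and 0.0843), of Vip (replicate 2 or 3, 0.0901) and of Dlg4 (replicate 1 or 2, 0.104). So did any 15 h array or vehicle replicate 1 for Cd68 (0.0903), and any 15 h array or vehicle replicate 2 for Mvd (0.0999). Slc17a7 was called only without vehicle replicate 3 or 5 or 8 h replicate 3 (0.177 otherwise), and Chordc1 only without vehicle replicate 3 or 5, 8 h replicate 2 or 3 or 24 h replicate 1 (0.153 otherwise). Counts of members also rested on single arrays. The 4 higher apoptosis genes numbered 2 without vehicle replicate 2 or 8 h replicate 2 or any 15 h array. The 3 lower ones numbered 0 without 15 h replicate 2 and 1 without vehicle replicate 1 or 15 h replicate 1 or 3. Of the ER chaperone list the lower genes numbered 0 without 15 h replicate 2 or 3, 1 without vehicle replicate 1 or 2 or 15 h replicate 1 and 2 without vehicle replicate 4. The higher one became 2 without 24 h replicate 1. Higher metallothionein, zinc and iron genes numbered 0 without vehicle replicate 1 or 3 or any 15 h array, 1 without vehicle replicate 2 or 4 or 24 h replicate 3 and 4 without 8 h replicate 3 or 24 h replicate 1. Lower ones numbered 1 without 15 h replicate 2 or 3. For the cell cycle list the higher genes numbered 0 without vehicle replicate 2, 3 or 4 or 15 h replicate 1 or 3 and 1 without vehicle replicate 1 or 15 h replicate 2 or 24 h replicate 2 or 3 or any 8 h array. The lower cell cycle genes numbered 0 without 15 h replicate 2 and 1 without 15 h replicate 1 or 3. Proteasome genes that rose numbered 0 without 15 h replicate 1 or 2. Those that fell numbered 0 without 15 h replicate 2 or 3 and 1 without 15 h replicate 1 or 24 h replicate 2 or any vehicle or 8 h array. Heat shock genes that rose numbered 4 without 8 h replicate 3, and interneuron markers that rose 1 without 24 h replicate 1 and 2 without vehicle replicate 5. Respiratory chain genes that rose numbered 1 without 15 h replicate 1 or 2. Microglia markers that rose numbered 0 without vehicle replicate 1 or any 15 h array and 2 without vehicle replicate 2. The cholesterol genes that fell numbered 0 without vehicle replicate 2 or any 15 h array and 2 without vehicle replicate 5. Lists without a called member gained some. Nitric oxide signalling genes that fell numbered 1 without vehicle replicate 5 and 3 without vehicle replicate 4. DNA repair genes that fell numbered 1 without 24 h replicate 1 and 2 without vehicle replicate 5, and 1 rose without vehicle replicate 1. Without 24 h replicate 1 a cytoskeleton gene fell, and without 15 h replicate 1 a vascular marker rose.

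At 24 h oligodendrocyte lineage and cell cycle genes had fallen. Hmox1 stood 85.1-fold above vehicle (log2 fold change 6.41, SE 0.49, adjusted p = 3.87e-05 by limma's moderated test) and Ptgs2 100.3-fold (6.65, SE 0.85, adjusted p = 0.000548). Gpr17, a receptor of oligodendrocyte precursors, fell by 5.11 on the log2 scale (SE 0.54, adjusted p = 0.000181), Olig1 fell by 4.22 (SE 0.17, adjusted p = 3.08e-07) and Tk1 fell by 4.96 (SE 0.63, adjusted p = 0.000530). Tagln, an actin-binding protein of smooth muscle, rose by 4.39 (SE 0.79) and Esm1, a secreted endothelial proteoglycan, by 5.11 (SE 0.74). Aurkb, a mitotic kinase, fell by 3.48 (SE 0.42, adjusted p = 0.000394). These 8 genes were called in all 14 fits that left out 1 array.

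Of 18193 genes, 612 were higher and 1624 lower at 24 h (72.6% lower), and 357 and 785 of them by at least 2-fold. After median centring there were 1005 higher and 1375 lower (57.8% lower), and after quantile normalization 210 and 363 (63.4% lower). The higher genes numbered 943 without 24 h replicate 1, 311 without replicate 2 and 336 without replicate 3. With the hybridisation-control split as a block the counts were 767 and 1960, and on the 10 arrays with higher controls 805 and 1281. A fit of these 8 arrays alone gave 305 and 914.

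Of 12 oligodendrocyte lineage markers 7 fell at 24 h, none rose and 5 did not pass (7 adjusted over the list alone). The list fell with camera adjusted p = 2.49e-07 (median -1.66) and kept its call with an estimated correlation (adjusted p = 0.0258). Olig2 (-3.83, SE 0.33), Pdgfra (-3.22, SE 0.27), the growth factor receptor of the precursors, and Cspg4 (-2.53, SE 0.29), the proteoglycan NG2, fell with Olig1 and Gpr17. Of 22 cell cycle genes 15 fell, none rose and 7 did not pass, with 18 lower and 1 higher when adjusted over the list alone (median -1.13, camera adjusted p = 1.54e-09), and the call held with an estimated correlation (adjusted p = 0.0216). They included Cdk1, the mitotic kinase (-1.54, SE 0.17), Rrm2, which makes deoxynucleotides (-1.70, SE 0.17), and Mki67, the proliferation antigen (-2.24, SE 0.27). The astrocyte list, at a median of 0.37, had 1 gene higher (Gja1, 1.30, SE 0.21) and 1 lower (Aldh1l1, lost without 24 h replicate 2, adjusted p = 0.0795) of 15 (camera adjusted p = 0.217). On the 10 arrays with higher hybridisation controls the astrocyte list passed (adjusted p = 0.0424), as it did without 24 h replicate 1 (0.00904), when 5 members were higher. With an estimated correlation, in all arrays, its adjusted p was 0.90.

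Among 22 p53 targets 12 rose at 24 h and none fell (15 adjusted over the list alone, median 1.03, camera adjusted p = 2.49e-11), and the call held with an estimated correlation (adjusted p = 0.0480). Bbc3 rose by 2.28 (SE 0.22) and Fas by 4.23 (SE 0.75), while Cdkn1a, at 1.34 (SE 0.45, adjusted p = 0.0787), did not pass. The list shares 7 of its members with other lists. Of 20 NRF2 targets 13 rose and none fell (18 adjusted over the list alone, camera adjusted p = 6.20e-18, lost at adjusted p = 0.0566 with an estimated correlation), with Osgin1 (5.41, SE 0.71) and Gsta4 (3.29, SE 0.23) among them. Of 20 immediate early genes 13 rose and none fell (16 adjusted over the list alone, median 1.30, camera adjusted p = 3.69e-16), and the call held with an estimated correlation (adjusted p = 0.0155). Bdnf stood at 0.41 (SE 0.28, adjusted p = 0.414).

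Of 26 ATF4 and CHOP targets 12 rose and none fell at 24 h (15 adjusted over the list alone, camera adjusted p = 5.66e-11), a call lost at adjusted p = 0.198 with an estimated correlation. Ddit3 rose by 2.31 (SE 0.25) and Slc7a11 by 3.09 (SE 0.26). Of 17 NF-kB and cytokine genes 4 rose and none fell (4 adjusted over the list alone, camera adjusted p = 0.00312), and the call held with an estimated correlation (adjusted p = 0.0480). Il6, the gene of interleukin 6, rose by 4.21 (SE 0.82). Of 20 autophagy and lysosome genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00110, lost at adjusted p = 0.424 with an estimated correlation), with Sqstm1 at 2.47 (SE 0.32) and Lamp2, a lysosomal membrane protein, at 0.85 (SE 0.18). Of 17 heat shock genes 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.0226), with adjusted p = 0.370 with an estimated correlation and 0.0658 without 24 h replicate 3. Hspb8, a small chaperone, rose by 2.59 (SE 0.35). The 7 higher autophagy genes numbered 3 without 24 h replicate 3 and 4 without vehicle replicate 2 or 3 or 24 h replicate 2, and the lower one 0 without 24 h replicate 1 or 3. Heat shock genes that rose numbered 4 without 24 h replicate 1. The heat shock gene that fell became 0 without vehicle replicate 1, 2 or 4 or 8 h replicate 1 or 24 h replicate 2 or 3 or any 15 h array.

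The remaining lists did not pass camera at 24 h. Of 22 apoptosis genes 4 rose and 1 fell, the latter Mcl1, a survival protein (-0.69, SE 0.13). The 4 that rose, Fas, Bbc3, Pmaip1 and Tnfrsf10b, are also in the p53 list and were counted there too. Of 19 members of the ER chaperone list 2 rose and 3 fell, with Herpud1 at 1.59 (SE 0.18) and Creld2 at -0.93 (SE 0.14). Of 21 HIF1 and glycolysis genes 2 rose and 1 fell, with Slc2a1 at 3.50 (SE 0.33) and Egln3, an oxygen sensor, at -0.89 (SE 0.16). Cd68, a lysosomal protein of phagocytes, was the 1 of 15 microglia markers that rose (3.14, SE 0.43), and Pdgfrb, a receptor of pericytes, the 1 of 16 vascular markers that fell (-2.12, SE 0.36). Cox7c (1.79, SE 0.22) and Atp5c1 (0.90, SE 0.20) rose among 27 respiratory chain genes, with 5 higher without 24 h replicate 1. The respiratory chain list, at a median of 0.17 and camera adjusted p = 0.0621, passed with a pseudocount of 1 (0.0399), quantile normalization (0.0207), median centring (0.0109), array weights (0.00289) and on the 10 arrays (0.00199). It also passed without 24 h replicate 1 (0.000145) or vehicle replicate 1 (0.0284), 2 (0.0496) or 3 (0.0446), so the absence of a call rested on the setting. With an estimated correlation, in all arrays, its adjusted p was 0.90. In the proteasome list 1 of 31 rose and 1 fell, in the interneuron list 1 of 16 rose and 3 fell (Dlx1, -1.85, SE 0.27), and in the cholesterol list 1 of 15 rose and 1 fell. The metallothionein, zinc and iron list had 1 higher and 2 lower of 13, and DNA repair 1 higher and 1 lower of 20, the latter Brca2 (-0.95, SE 0.18). A single gene fell among 22 synaptic genes (Gria2), 16 neuronal cytoskeleton genes (Nefh) and 18 nitric oxide signalling genes (Pde5a). Leaving out 1 array ended the calls of Gria2 (vehicle replicate 1, 2 or 3 or 24 h replicate 2 or 3, highest adjusted p = 0.138), of Nefh without 24 h replicate 3 (0.0880) and of Pde5a without 24 h replicate 2 (0.0956). Nos1 stood at 0.23 (SE 0.26, adjusted p = 0.642 by limma's moderated test). The DNA repair gene that rose, Lig3, was called lower with the probe set of least vehicle spread. Counts of members rested on single arrays here too. Of the apoptosis genes the lower numbered 2 without vehicle replicate 3 or 8 h replicate 3. Of the ER chaperone list the higher genes numbered 1 without vehicle replicate 2, 3, 4 or 5 or 24 h replicate 2 or 3 or any 8 h or 15 h array. Lower HIF1 and glycolysis genes numbered 2 without vehicle replicate 2. Interneuron markers that fell numbered 1 without vehicle replicate 1, 3 or 5 or 15 h replicate 2 or 24 h replicate 2 or 3. The 1 that rose became 0 without 24 h replicate 2 or 3. Higher metallothionein, zinc and iron genes numbered 0 without vehicle replicate 3 or 24 h replicate 2 or 3 and 2 without 8 h replicate 2 or 24 h replicate 1. Lower ones numbered 1 without vehicle replicate 1, 2 or 4 or 24 h replicate 1 or 2. The DNA repair genes that rose numbered 0 without vehicle replicate 2, 3, 4 or 5 or 8 h replicate 2 or 15 h replicate 2 or 3 or 24 h replicate 2 or 3. Those that fell numbered 2 without vehicle replicate 5 or 8 h replicate 2 or 3 or 24 h replicate 1. Proteasome genes that rose numbered 3 without 24 h replicate 1. Those that fell numbered 0 without 24 h replicate 1 or 2. Cholesterol genes that rose numbered 0 without vehicle replicate 4 or 5 or 24 h replicate 2 or 3. Those that fell numbered 0 without 24 h replicate 1 or 3 and 2 without vehicle replicate 4. Nitric oxide signalling genes that rose numbered 1 without 8 h replicate 3 and 2 without 24 h replicate 1. Those that fell numbered 0 without 24 h replicate 2 and 2 without vehicle replicate 4. Without 24 h replicate 1 the cytoskeleton list had 1 gene higher and 2 lower, and without vehicle replicate 2 or 8 h replicate 1 a synaptic gene rose.

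With the hybridisation-control split as a block, every list called against vehicle was still called, with medians of 2.50 for immediate early genes at 8 h, 0.97 for astrocyte markers at 15 h, and -1.64, -1.16, 1.28 and 1.03 for oligodendrocyte lineage, cell cycle, NRF2 and p53 genes at 24 h. The list means were also compared within the 2 sets of arrays that the hybridisation controls separated, with 2 treated against 3 vehicle arrays in the higher set and 1 against 2 in the lower. At 8 h the treated minus vehicle difference in the higher and the lower set was 2.47 and 2.45 for the immediate early genes, 0.77 and 0.92 for the NRF2 targets, 0.38 and 0.74 for the p53 targets, and 0.59 and 0.45 for the ATF4 and CHOP targets. At 24 h it was -1.82 and -1.87 for the oligodendrocyte lineage markers, -1.07 and -1.14 for the cell cycle genes, 1.79 and 1.18 for the immediate early genes, 2.03 and 1.32 for the NRF2 targets, 1.40 and 0.88 for the p53 targets. For the ATF4 and CHOP targets it was 1.29 and 0.65, for the NF-kB and cytokine genes 1.10 and 1.07, for autophagy and lysosome 0.53 and 0.16, and for heat shock 0.47 and 0.23. Astrocyte markers at 24 h were at 0.27 in the higher set and -0.26 in the lower. With 3 arrays of each group in the higher set at 15 h, the difference was 2.11 for immediate early genes, 1.64 for NRF2 targets, 0.98 for p53 targets, 1.01 for ATF4 and CHOP targets, 0.26 for autophagy and lysosome, 0.87 for NF-kB and cytokine genes, 0.89 for astrocyte markers and -0.68 for oligodendrocyte lineage markers. At least as many lists as in the real split were called in 25, 4 and 10 of the 56 splits of the arrays at 8, 15 and 24 h, the real split included, so that chance was not excluded for the number of lists.

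**Figure D2:**
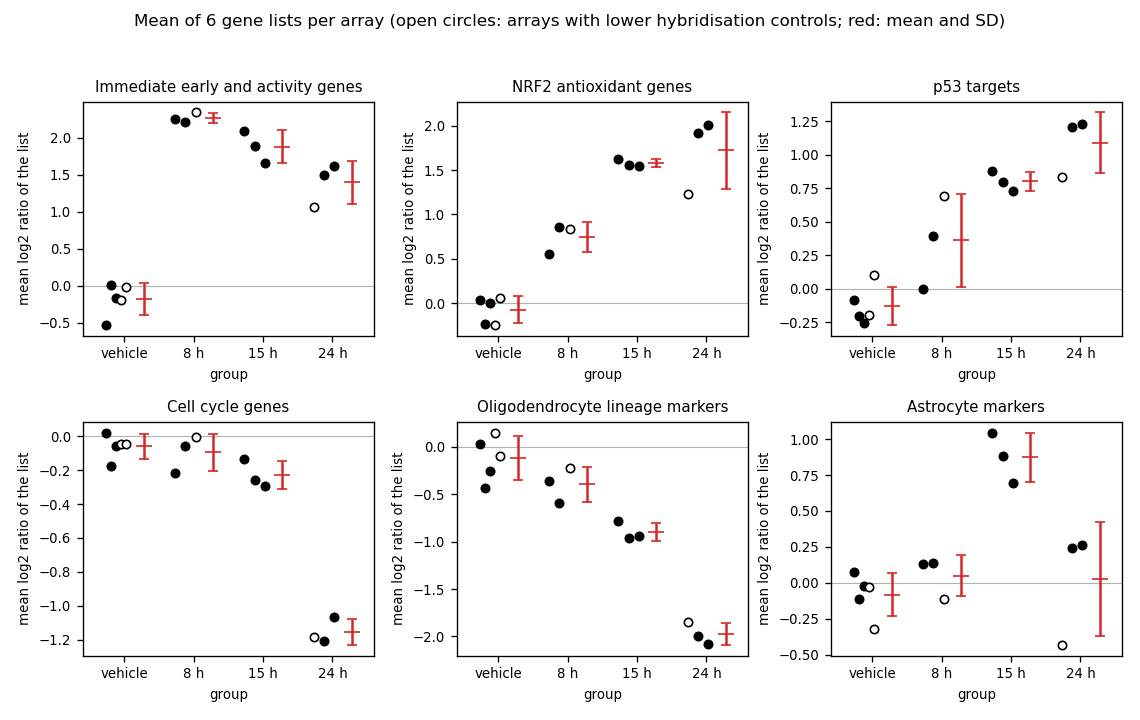
Each panel plots the mean log2 ratio to the vehicle mean over the members of 1 gene list on each of the 14 arrays by group, with open circles for the 4 arrays with lower hybridisation controls and red marks for the group mean and SD. Immediate early genes lay 2.46 above vehicle at 8 h and 1.58 at 24 h, astrocyte markers 0.96 above at 15 h, and oligodendrocyte lineage markers and cell cycle genes at -1.85 and -1.10 against vehicle at 24 h.

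Between 8 and 15 h (n = 3 against 3) few single genes differed. Crabp2, a retinoic acid carrier, was 18.2-fold higher at 15 h (log2 difference 4.19, SE 0.49, adjusted p = 0.0394 by limma's moderated test), and Gsta4 was 3.79-fold higher (1.92, SE 0.26, adjusted p = 0.0493). Slitrk6, a neuronal membrane protein, was 15.9-fold lower (-3.99, SE 0.64, adjusted p = 0.0493). In all 11 genes were higher and 6 lower, against 2154 at an unadjusted p under 0.05. The total was 0 under quantile normalization, 1 with the hybridisation-control block, 1 with the replicate block and 394 with array weights. Each of the 14 fits that left out 1 array also moved this count. It was 0 without vehicle replicate 1, 8 h replicate 1, 8 h replicate 2, 15 h replicate 2 or 24 h replicate 2, 1 without vehicle replicate 2, 8 h replicate 3 or 15 h replicate 1, and 2 and 3 without vehicle replicates 3 and 4. It was 4 without vehicle replicate 5, 15 h replicate 3 or 24 h replicate 3, and 30 without 24 h replicate 1. None of the 9 named genes called here was called in all of these fits, with Crabp2 lost without vehicle replicate 1, 8 h replicate 1 or 2, 15 h replicate 1 or 2 or 24 h replicate 2 (highest adjusted p = 0.114). Gsta4 was called only without 24 h replicate 1 or 3, and Slitrk6 only without 15 h replicate 3 or 24 h replicate 1 (0.226 otherwise in both).

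By camera 8 lists differed between 8 and 15 h, and none did with an estimated correlation. The astrocyte markers were higher at 15 h (median 0.85, camera adjusted p = 8.15e-11, 0 of 15 members called, 12 adjusted over the list alone), with adjusted p = 0.162 with an estimated correlation, and so were the NRF2 targets (median 0.60, camera adjusted p = 3.79e-13, 2 of 20 members called, 8 adjusted over the list alone), with adjusted p = 0.163 with an estimated correlation. The p53 targets (median 0.17, camera adjusted p = 0.00215, then adjusted p = 0.480 with an estimated correlation) and the ATF4 and CHOP targets (median 0.27, camera adjusted p = 0.000132, then adjusted p = 0.671 with an estimated correlation) were higher. The NF-kB and cytokine genes (median 0.45, camera adjusted p = 0.0458, then adjusted p = 0.192 with an estimated correlation) and the autophagy and lysosome genes (median 0.18, camera adjusted p = 0.0210, then adjusted p = 0.715 with an estimated correlation) were higher too. The immediate early genes were lower (median -0.38, camera adjusted p = 0.00876, then adjusted p = 0.480 with an estimated correlation), as were the oligodendrocyte lineage markers (median -0.39, camera adjusted p = 0.0256, then adjusted p = 0.386 with an estimated correlation). The oligodendrocyte call was lost with the hybridisation-control split as a block (adjusted p = 0.0743) and without 8 h replicate 3 (0.118), 15 h replicate 2 (0.118) or 15 h replicate 3 (0.0680), and the immediate early call without 15 h replicate 3 (0.121). The autophagy call was lost without 8 h replicate 2 (0.0557) or 15 h replicate 1 (0.167), and the NF-kB call without 8 h replicate 2 (0.182), 15 h replicate 1 (0.133) or 3 (0.0630), 24 h replicates 1 to 3 (0.0521, 0.0573 and 0.0590), 8 h replicate 1 (0.0510) or vehicle replicate 2 (0.0508). Quantile normalization ended the oligodendrocyte (0.0504), p53 (0.0504), autophagy (0.0732) and NF-kB (0.210) calls, and median centring that of NF-kB (0.0625). The called NRF2 members numbered 0 without 24 h replicate 2 or any vehicle, 8 h or 15 h array and 1 without 24 h replicate 3, and the astrocyte members 1 without 24 h replicate 1.

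Between 15 and 24 h (n = 3 against 3) oligodendrocyte lineage and cell cycle genes fell. Olig1 fell by 2.50 on the log2 scale (SE 0.19, adjusted p = 0.000437 by limma's moderated test), Pdgfra fell by 2.61 (SE 0.31, adjusted p = 0.00436) and Cdk1 fell by 2.12 (SE 0.18, adjusted p = 0.000838). Map3k1, a kinase upstream of JNK, fell by 2.65 (SE 0.28, adjusted p = 0.00307). These 4 of the 13 named genes called here were called in all 14 fits that left out 1 array, whereas Aurkb (-2.81, SE 0.47) was called only without vehicle replicate 5 or 24 h replicate 1 (highest adjusted p = 0.149 otherwise) and Olig2 (-2.05, SE 0.37) only without 8 h replicate 3 or 24 h replicate 1 (0.173 otherwise). In all 9 genes were higher and 44 lower. Quantile normalization gave a total of 3, median centring 84 and the replicate block 8. The total of 53 was 20, 26 and 28 without 15 h replicates 1, 2 and 3, 32 without 24 h replicate 2, 30 and 33 without vehicle replicates 1 and 2, and 31, 30 and 32 without 8 h replicates 1, 2 and 3. A fit of these 6 arrays alone called 0 genes by limma, with 1767 genes at an unadjusted p under 0.05 when all 14 arrays were fitted.

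The oligodendrocyte lineage list fell between 15 and 24 h with 4 of 12 members lower (7 adjusted over the list alone, median -1.07, camera adjusted p = 1.18e-08), and the cell cycle list with 4 of 22 (13 lower and 1 higher adjusted over the list alone, median -0.84, camera adjusted p = 2.39e-17). Both calls held with an estimated correlation (adjusted p = 0.0208 and 0.00453). The astrocyte list went down again (median -0.66, 0 of 15 members called lower, 8 adjusted over the list alone, camera adjusted p = 8.74e-11), with adjusted p = 0.162 with an estimated correlation. The immediate early genes were lower (median -0.47, camera adjusted p = 0.000118, then adjusted p = 0.218 with an estimated correlation) and the p53 targets higher (median 0.31, camera adjusted p = 0.00933, then adjusted p = 0.614 with an estimated correlation). Synaptic genes (median 0.30, camera adjusted p = 0.0110, then adjusted p = 0.715 with an estimated correlation) and neuronal cytoskeleton genes (median 0.23, camera adjusted p = 0.0458, then adjusted p = 0.806 with an estimated correlation) were higher at 24 h than at 15 h, with no single member called. Without 24 h replicate 3 the p53 (adjusted p = 0.0600), synaptic (0.0567) and cytoskeleton (0.205) calls were lost, and without 24 h replicate 2 the synaptic (0.0611) and cytoskeleton (0.325) calls. The cytoskeleton call was also lost without 15 h replicate 1 (0.123) or 3 (0.168), 8 h replicates 1 to 3 (0.0514, 0.0557 and 0.0537) or vehicle replicate 2 (0.0568), with the replicate block (0.0505) and under quantile normalization (0.127), which also ended the p53 call (0.0504). The 4 lower oligodendrocyte genes numbered 2 without vehicle replicate 1, 2, 3 or 5 or 8 h replicate 1 or 2 or any 15 h array. The 4 lower cell cycle genes numbered 1 without 15 h replicate 1 and 2 without vehicle replicate 1, 2 or 4 or 15 h replicate 2 or 3 or 24 h replicate 2 or any 8 h array. Without 24 h replicate 1, and on the 10 arrays, which lack it, the astrocyte median was -0.37. In the fit without that array NRF2 (0.000522), ATF4 and CHOP (0.0417), proteasome (0.0122) and respiratory chain genes (0.00354) passed camera as higher at 24 h, while in all arrays none of the 4 passed with an estimated correlation (lowest adjusted p = 0.932).

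Over the whole time course 2054 genes differed from vehicle in the moderated F test of limma, 76 of which were called at no single time. Quantile normalization left 488 and the replicate block 604. In the same direction at all 3 times, 55 genes were higher and 90 lower, among them Fos, Hmox1 and Olig1, while 298 higher and 940 lower genes were called at 15 and 24 h but not at 8 h, and 6 and 11 at 8 h alone. These are counts of calls, not tests of a difference between times. Cdk1, Cdc20 and Ube2c, genes of mitosis, were higher at 15 h (0.58, 1.00 and 0.95) and lower at 24 h (-1.54, -1.55 and -1.37), and differed between those times (adjusted p = 0.000838, 0.00592 and 0.00399 by limma's moderated test). The cell cycle list as a whole did not rise at 15 h (2 higher and 3 lower of 22, median -0.17, camera adjusted p = 0.720). With 1 array left out, the rise at 15 h was called for Cdk1 only without vehicle replicate 5 or 24 h replicate 1 (highest adjusted p = 0.183 otherwise), and for Cdc20 only without vehicle replicate 5, 8 h replicate 2 or 3, 15 h replicate 2 or 24 h replicate 1 (0.188 otherwise). For Ube2c it was lost without 15 h replicate 1 or 2 (0.0908), while the difference between 15 and 24 h held in all 14 fits for these genes. Ets1, an endothelial and lymphoid transcription factor, rose at 8 h (1.31, SE 0.19) and fell by 0.81 at 24 h, the former lost without 8 h replicate 2 (adjusted p = 0.0818). Cdc20, Ube2c and Ets1 were chosen after their values were seen, from the 6 genes called in opposite directions at 2 times. For Cdc20 and Ube2c the test between 15 and 24 h was largely fixed by this choice.

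The 3 comparisons share the same vehicle arrays, so their calls overlap in part by construction. Of the calls at 15 and 24 h, 353 higher and 1030 lower genes were shared, against 20.8 and 142 for independent lists of these sizes. With quantile normalization 327 were shared, higher and lower together. In 100 simulations of unchanged groups against the same vehicle arrays 0 and 0 were shared on average. Unchanged groups yield hardly any calls, so this 0 was fixed beforehand and gives no baseline for lists of these sizes. At 8 and 15 h 62 and 96 were shared (2.42 and 9.77 for independent lists), and at 8 and 24 h 58 and 95 (2.39 for independent lists of higher genes). With the vehicle arrays split between the comparisons, the median overlap over 20 splits was 175 and 449.5, 29.5 and 7, and 26 and 6.5 for the same pairs. Each comparison then had fewer vehicle arrays, so lost power and the removal of shared arrays cannot be told apart in these counts. Across genes, which are not independent replicates, the log2 fold changes at 15 and 24 h correlated at 0.607, against 0.374 in the simulations. The covariance was 0.347 against 0.113, a difference of 0.235. For 8 with 15 h the correlation was 0.520 and the covariance 0.238 (difference 0.125), and for 8 with 24 h they were 0.505 and 0.238 (0.125). With the vehicle arrays split, the median correlation was 0.342, 0.223 and 0.214 for these pairs in turn, and the median covariance 0.237, 0.127 and 0.127.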

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

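The tests of array scaling and of glial shares for oligodendrocyte markers, of precursor against myelin genes, of the neuronal share for astrocyte markers and of scaling for the share of lower genes were chosen only after the result was seen. The gene lists, comparisons and rules for naming genes were set before the data were examined.

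Within the vehicle group 4 of 141 checks found an array far from the other 4, against 7.05 by chance, since chance finds about 1 in 20 groups. These were the 3' to 5' log2 ratio of beta-actin in vehicle replicate 4 (0.25), the mean of the ATF4 and CHOP targets in vehicle replicate 5 (0.42), A230057D06Rik in vehicle replicate 3 (1.66) and the proteasome gene Psmc6 in vehicle replicate 3 (-0.15).

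Oligodendrocyte lineage markers lay at a median of -1.66 against vehicle at 24 h, and their median differed by -1.07 between 15 and 24 h and by -0.39 between 8 and 15 h (adjusted p = 0.0208 and 0.386 with an estimated correlation). A batch effect of the arrays with lower hybridisation controls is argued against by a median of -1.64 with the batch as a block, and array scaling by -1.56 after median centring. A lower share of all glial cells would lower astrocyte markers too. Their median was 0.37 at 24 h, with the list not called (camera adjusted p = 0.217). Against vehicle their mean was 0.27 in the higher-control arrays and -0.26 in the lower-control ones. From 15 to 24 h their median difference was -0.66. The oligodendrocyte lineage means were -1.82 and -1.87 in the same 2 sets. Astrocyte markers thus did not fall as far, but their expression per cell may have changed, so a lower glial share was not excluded. The precursor genes fell further than the myelin genes (difference of medians -3.33), but without signal levels a loss of precursors cannot be told apart from myelin genes too weak to measure. A response of oligodendrocyte precursors to NOC-18 may remain, as a hypothesis found and tested on the same arrays. It cannot be told apart from an effect of time in culture, since the harvest time of the vehicle cultures was not given.

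Astrocyte markers had a median difference of 0.85 from 8 to 15 h and of -0.66 from 15 to 24 h (-0.37 without 24 h replicate 1 or on the 10 arrays with higher controls), each with adjusted p = 0.162 with an estimated correlation. The batch of arrays is argued against by a difference of 0.89 from vehicle at 15 h among arrays with higher controls, and array scaling by a median of 1.24 after centring. A lower share of neurons alone would raise all glial markers alike, while the oligodendrocyte lineage median was -0.88 at 15 h. This does not decide the question, since those markers may have fallen for a reason of their own. Synaptic and neuronal cytoskeleton medians were -0.36 and -0.20 at 15 h (camera adjusted p = 0.0653 and 0.527). That is the direction a lower share of neurons predicts. With the batch as a block they were -0.54 and -0.33 (0.00205 and 0.0448). At 24 h the 2 medians were -0.16 and 0.12 against vehicle. From 15 to 24 h they differed by 0.30 and 0.23 (camera adjusted p = 0.0110 and 0.0458). A lasting loss of neurons does not predict that rise, but the calls were lost with an estimated correlation (adjusted p = 0.715 and 0.806). A lower share of neurons at 15 h was thus left open. A change in the astrocytes themselves may also remain and was not tested apart from a change in their number.

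After median centring 51.0% of the calls at 15 h and 57.8% at 24 h were lower. Centring itself pulls the calls towards balance, so these shares decide nothing. Among the arrays with higher controls, scaling would have put the hybridisation controls of the treated arrays below those of vehicle, but they stood at 1.16 to 1.36 at 15 h and 1.36 and 1.37 at 24 h, against 1.08 to 1.20 in vehicle. In those arrays the controls thus gave no sign of a lower scale. Among the arrays with lower controls they went the other way. There 24 h replicate 1 stood at 0.720, against 0.770 and 0.821 in vehicle, and its median ratio of 0.842 was the lowest of all arrays. Without that array 61.6% of the calls at 24 h were lower. The controls are not measured against total RNA here, and scaling and a true excess of lower genes cannot be told apart.

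Other lists also differed between times by camera with the preset correlation, but with an estimated correlation none of those between 8 and 15 h did, and of those between 15 and 24 h only the cell cycle genes (adjusted p = 0.00453) did. From 8 to 15 h the median difference was 0.60 for NRF2 targets, 0.45 for NF-kB and cytokine genes, 0.27 for ATF4 and CHOP targets, 0.18 for autophagy and lysosome, 0.17 for p53 targets and -0.38 for immediate early genes. From 15 to 24 h it was 0.31 for p53 targets, 0.30 for synaptic transmission, 0.23 for neuronal cytoskeleton, -0.47 for immediate early genes and -0.84 for cell cycle genes.

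Single genes differed between 8 and 15 h by 4.19 (Crabp2), 3.68 (Cdrt4os1), 2.29 (Steap1), 2.25 (Dnaic1), 1.92 (Gsta4), -2.04 (Engase), -3.22 (Tsnaxip1), -3.26 (Itpr3) and -3.99 (Slitrk6). Between 15 and 24 h they differed by 4.00 (4930413E15Rik), 3.81 (A230057D06Rik), 3.10 (Pitpnm2os1), 3.00 (1700122O11Rik), 2.96 (Calhm2), -2.03 (Dnaic1), -2.05 (Olig2), -2.12 (Cdk1), -2.50 (Olig1), -2.61 (Pdgfra), -2.65 (Map3k1), -2.81 (Aurkb) and -3.38 (Fam89a).

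Among 10092 probe sets without a single gene symbol, which the comparisons of genes did not use, 3 were called at 8 h, 82 at 15 h and 162 at 24 h by limma with Benjamini-Hochberg adjustment.

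The real split and the other splits of the 8 arrays of a comparison into 3 and 5 were fitted on those 8 arrays alone. Their counts therefore differ from those of the fit of all 14 arrays. The real split called 44 genes at 8 h, 1633 at 15 h and 1219 at 24 h. Any of the other splits called at most 7, 4 and 10. Thus 1 of 56 splits gave as many at each time, the smallest share this test can give. Over the time course 2054 genes were called and at most 31 in another of the 100 splits (1 as large). No other division of these arrays that was tried gave such counts. Since the replicates may not be separate cultures, chance differences between cultures were not excluded. For the number of lists called, chance cannot be excluded: 25 of 56 splits gave at least the 4 lists of 8 h (highest other 11), 4 of 56 the 10 of 15 h (highest other 11) and 10 of 56 the 9 of 24 h (highest other 13). The split that parts the lower-control arrays from the rest called 6 lists and 7 genes among the 8 h and vehicle arrays, and 8 lists and 9 genes among the 24 h and vehicle arrays, while with that split as a block 110 genes were higher and 256 lower at 8 h. Between times the 10 splits of 3 against 3, fitted on the arrays compared alone, are too few. From 8 to 15 h the real split called 3 genes and the highest other 2 (1 of 10 as large). From 15 to 24 h both called 0 by limma (10 of 10 as large). The fit of all 14 arrays had 1767 genes at an unadjusted p under 0.05 there.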

How the results depend on the processing

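The 25th percentile pseudocount, the least-spread probe set, the 40% of genes left out and both settings of the hybridisation controls were chosen after seeing the data. The filters at the 40th and 60th percentile and the choice of the probe set with the highest mean were not run, because ratios carry no level, and weak signals could not be separated from strong ones. No list or named gene called in all arrays changed the sign of its median or log2 fold change in the settings in which it was followed, whereas lists not called did so 156 times. In 2 of these the list was then called, the microglia markers at 15 h with the batch block and on the 10 arrays. For these signs array weights were run on the lists but not on the named genes, and the least-spread probe set and some other settings on neither. Over all called genes, the least-spread probe set turned the sign of 3 at 8 h, 45 at 15 h and 66 at 24 h, of which 0, 7 and 14 were called the other way, among them Lig3 (0.95 to -0.84 at 24 h). It also left the immediate early gene Fosl2 at -0.088 instead of 1.07 at 8 h. No called gene turned in the other settings compared, which left out all probe sets taken singly, the 40% filter, fits of only the groups compared and the vehicle splits. For most called genes (183 at 8 h, 2154 at 15 h and 2112 at 24 h) all treated arrays lay beyond all vehicle arrays. Leaving out 1 array could not turn their sign. Genes named for the largest changes were chosen by that same rule, so for them this result was fixed beforehand. The trend and robust fit does not alter fold changes. Apart from heat shock genes at 24 h (adjusted p = 0.0658 without 24 h replicate 3), every list called against vehicle stayed called under the 21 alternatives, the estimated correlation aside, with which 14 list calls against vehicle and 13 between times were lost. Named genes lost a call 100 times under quantile normalization, 80 with the replicate block, 56 on the 10 arrays, 25 with a pseudocount of 1, 12 under median centring, 11 with the batch block and 503 times over the 14 fits without 1 array. The cause was not tested for the moved counts, except where fewer arrays or genes entered.

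Between 8 and 15 h, where 17 genes differed, there were 38 with a pseudocount of 1, 34 with one at the median ratio (0.939) and 9 with one at the 25th percentile (0.659). Quantile normalization gave 34 genes lower at 8 h, 256 higher and 346 lower at 15 h, 210 and 363 at 24 h, 0 between 8 and 15 h by limma, 3 between 15 and 24 h and 488 over the time course, with shared calls of 72 (8 and 15 h), 64 (8 and 24 h) and 327 (15 and 24 h). Median centring gave 62 lower at 8 h, 989 and 1031 at 15 h, 1005 higher at 24 h and 84 between 15 and 24 h. Of all probe sets 152 and 272 were called at 8 h, 1542 and 3749 at 15 h, 1564 and 3941 at 24 h, 1 between 8 and 15 h and 4989 over the time course. The least-spread probe set, which selects low vehicle variance, gave 169 and 666 at 8 h, 3008 lower at 15 h, 943 and 2952 at 24 h, 136 and 109 between successive times and 3955 over the time course. With trend and robust variances there were 27 and 3 at 8 h, 0 between 8 and 15 h and 32 between 15 and 24 h. Array weights gave 131 and 355 at 8 h, and 394 and 109 between successive times. Without the noisiest 40% of genes there were 150 and 493 at 8 h, 180 and 181 between successive times and 3242 over the time course. With the batch block there were 110 and 256 at 8 h and 1 between 8 and 15 h, and on the 10 arrays 56 lower at 8 h and 4 and 29 between successive times. Fits of only the groups compared gave 29 and 15 at 8 h, 305 and 914 at 24 h, and 3 and 0 between successive times. With the vehicle arrays split, which leaves fewer vehicle arrays per comparison, shared calls were 36.5, 32.5 and 624.5.

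With the replicate block, which spends degrees of freedom on the replicate number, there were 28 higher and 4 lower at 8 h, 361 and 675 at 15 h, 919 lower at 24 h, 1 and 8 between successive times and 604 over the time course. The numbers did not pair the arrays: same-numbered arrays correlated at -0.147 to 0.0491 in their deviations from the group means, and 0 of 9 treated arrays correlated best with their own number.

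Leaving out each array in turn gave 17 to 88 genes higher and 6 to 151 lower at 8 h, 261 to 737 and 725 to 1736 at 15 h, 311 to 943 and 1123 to 1609 at 24 h, 0 to 30 between 8 and 15 h, 20 to 50 between 15 and 24 h and 1456 to 2400 over the time course.

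Lists not called in all arrays passed camera in some settings, all at the preset correlation, and in all arrays none of them passed with an estimated correlation. At 8 h these were synaptic genes (0.0260 with the replicate block, 0.0314 without 8 h replicate 1), microglia markers (0.0326 with the replicate block) and astrocyte markers (0.0378 after quantile normalization). Oligodendrocyte lineage markers passed too (0.0395 with a pseudocount of 1, 0.0379 without vehicle replicate 2), as did NF-kB and cytokine genes (0.0267 without 8 h replicate 2, 0.0498 without vehicle replicate 4). At 15 h the synaptic genes passed (0.0465 with array weights, 0.0399 with a pseudocount of 1, 0.0124 with the replicate block, 0.0257 without 15 h replicate 2, 0.0397 without 24 h replicate 1, 0.0498 and 0.0227 without vehicle replicates 4 and 5). Heat shock genes passed there in 4 settings (0.0311 after centring, 0.0399 with a pseudocount of 1, 0.0205 after quantile normalization, 0.0344 without vehicle replicate 1). So did respiratory chain genes (0.0104 after centring, 0.0112 after quantile normalization, 0.0488 without 15 h replicate 3, 0.0425 without vehicle replicate 1). At 24 h they were apoptosis genes (0.0470) and microglia markers (0.0308) with the replicate block, astrocyte markers with array weights (0.0467) and glycolysis genes on the 10 arrays (0.0273). Between 8 and 15 h respiratory chain genes passed after centring (0.0206), without 8 h replicates 1 and 2 (0.0203 and 0.00945), 15 h replicate 3 (0.0306), 24 h replicate 1 (0.0239) and vehicle replicate 5 (0.0487). Heat shock genes passed there with a pseudocount of 1 (0.0445) and synaptic genes on the 10 arrays (0.0106). Between 15 and 24 h NRF2 targets passed with array weights (0.00937) and on the 10 arrays (0.000298), respiratory chain genes with the batch block (0.0385) and on the 10 arrays (0.000621), and ATF4 and CHOP targets and proteasome subunits on the 10 arrays (0.0102 each).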

Other observations

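The 6 gene lists below were chosen after the data were seen, and the p-values are adjusted over 6 tests at each time. Targets of SRF and YAP, factors that answer actin tension, had 19 members measured, of which 1 rose at 8 h, 7 at 15 h and 3 at 24 h, and none fell. Camera gave adjusted p = 0.000267, 2.73e-08 and 2.60e-05 at these times, and adjusted p = 0.349, 0.0708 and 0.194 with an estimated correlation. At 24 h the higher members numbered 6 without 24 h replicate 1, and 1 fell without 24 h replicate 3. At 8 h they numbered 2 without vehicle replicate 5 or 24 h replicate 1, and 0 without vehicle replicate 1, 2, 3 or 4 or any 8 h or 15 h array. Flna, an actin crosslinker, rose by 1.26 at 15 h and 1.12 at 24 h (SE 0.16), and Srf rose by 1.57 and 1.56 (SE 0.28), both in all 14 fits without 1 array. Of 18 Notch and progenitor genes 8 fell at 24 h and 2 rose (median -0.63, camera adjusted p = 0.00579, adjusted p = 0.194 with an estimated correlation). At 15 h 4 rose and 5 fell (median -0.19, camera adjusted p = 0.968), or 2 and 3 without 15 h replicate 1 or 2, and at 8 h 1 fell (camera adjusted p = 0.648), a gene not called without vehicle replicate 1 or 8 h replicate 1 or 2. Those that fell at 24 h included Sox2, a progenitor transcription factor (-1.32), and Lfng, a Notch modifier (-2.36), and the 2 that rose, Nes and Vim, are filament genes whose calls were lost without 24 h replicate 2 or 3 (highest adjusted p = 0.0744 and 0.0980).

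The 23 cytosolic ribosomal protein genes had a median of 0.36 at 24 h with no single gene called (camera adjusted p = 2.60e-05, adjusted p = 0.352 with an estimated correlation), but 14 higher without 24 h replicate 1. At 15 h their median was 0.32 (camera adjusted p = 4.05e-05, adjusted p = 0.526 with an estimated correlation), and at 8 h they did not pass (0.425). Interferon-inducible genes (1 higher and 1 lower of 18, camera adjusted p = 0.701, estimated 0.869), axon injury genes (3 and 1 of 18, 0.169, estimated 0.424) and histone genes (2 and 2 of 8, 0.934, estimated 0.941) did not pass camera at 24 h, nor at 8 or 15 h (lowest adjusted p = 0.130 and 0.195). Their counts at 24 h rested on single arrays. The higher interferon gene was called only without vehicle replicate 2, 3 or 4, and the lower one only without vehicle replicate 3 or 24 h replicate 1. Lower axon injury genes numbered 0 without 24 h replicate 2 and 2 without vehicle replicate 2, and higher histone genes 1 without 24 h replicate 2 or 3.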
